A study of Mus musculus with 3 samples.

How the data were processed

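The data were single-cell RNA counts from dorsal skin epithelium of wild-type mouse embryos (strain C57BL/6JOlaHsd) at embryonic day 14.5, when the first hair follicle placodes, small thickenings of the epidermis, are forming. Per the labels' protocols, epithelium was parted from mesenchyme with Dispase II, the sheets of 3 to 4 littermates were pooled per sample, and cells were freed with TrypLE and stained for MAdCAM-1, an adhesion molecule on the surface of placode cells. Live cells were then sorted either as total epithelium or as MAdCAM-1-positive, placode-enriched cells, and libraries were made with 10x Genomics Chromium 3' chemistry, version 2, which marks each captured RNA molecule with a unique molecular identifier (UMI). There was 1 total epithelium library and there were 2 placode-enriched libraries, stated by the series design to be biological replicates.

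The deposited values were whole UMI counts per gene and cell, per the file headers and the values themselves, with no normalization. Cell Ranger, Seurat and the mouse genome build mm10 are named, without versions, per the submitters' processing notes; the gene annotation version, the strand setting and the filters on cells were not given in the sources used here. The total epithelium library had a table of its own and the 2 placode-enriched libraries shared a table, in which the number at the end of each cell barcode was taken as the number of the library. A swap of the 2 numbers would change only the names of these libraries. The tables held 14959 and 15900 genes, and the 14656 genes in both were used; the others held 0.00685% and 0.0142% of the UMIs. In the tables every cell had at least 2006 genes and at most 4.98% mitochondrial UMIs, so the filter set before the data were examined (500 genes, 10% mitochondrial UMIs) and the stricter one of 1500 genes removed 0 cells and their alternatives gave no other value.

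Everything that follows was computed from the deposited counts. Doublets, droplets holding more than 1 cell, were called per library with scrublet in scanpy 1.11.5 at an expected rate of 0.05. The caller marked 9, 4 and 3 cells (0.562%, 0.265% and 0.191%), which were removed. These are few for droplet data, so doublets can remain among the 1592, 1507 and 1568 kept cells. Cells were clustered with the Leiden method (igraph 0.11.9, resolution 1, 20 neighbours, 30 principal components of 1000 variable genes, 10000 counts per cell before the log). To keep the tested genes from defining the clusters, the symbols were parted into 2 sets by an arbitrary hash, of 7368 and 7288 genes. Only the first set was used to cluster, without marker genes and gene lists, which left 7133 genes. Class contrasts were tested on the second set plus the lists.

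The 10 clusters were named from markers fixed before the data were examined. A placode-like cluster needed 6 of 9 markers (among them Dkk4, Edar, Shh, Fgf20 and Bmp2) at 25% or more of the highest cluster's level, a basal epidermis-like one 7 of 7 (Krt5, Krt14, Krt15, Trp63, Col17a1, Itga6, Itgb4) at 50%, a suprabasal-like one 4 of 8 (Krt1, Krt10, Krtdap, Sbsn, Dmkn, Ovol1, Cnfn, Calml3) at 25% and a melanoblast-like one 5 of 6 at 50%. These numbers were set after the clusters had been seen, and the suprabasal one was loosened so that it also worked at other resolutions, which left the main class as it was. The clusters that met none of them stayed unnamed and held 4.59%, 19.6% and 20.9% of the cells of the total epithelium library and of placode-enriched libraries 1 and 2. Each of these clusters met 6 of the 7 basal markers and fell short only on Krt15. Placode-like cells came from 3 clusters and basal epidermis-like cells from 3. No naming rule was set for Schwann, endothelial, immune, muscle, erythroid, fibroblast and periderm cells, so their markers could name no cluster. Of the endothelial and immune markers 1 each was in both tables, and of the Merkel cell markers 0.

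Cells are not replicates, so UMIs were summed per library and class. Class contrasts used edgeR 4.0.16 (R 4.3.3), its quasi-likelihood test with TMM scaling, filterByExpr and the library as a block, over 6 sums from 3 libraries. The same test compared the placode-enriched with the total epithelium libraries, over all cells and over placode-like cells. There the lone total epithelium library was assumed to vary like the placode-enriched libraries, and 1 residual degree of freedom was left. P-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. Within the placode-like class, cells with a Shh UMI and no Sox9 UMI were set against cells with a Sox9 UMI and no Shh UMI. Co-detection of these genes was compared with 100000 permutations within library and depth decile. The 18 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation, and fry, whose p asks whether a list moved on balance in either direction. Camera with an estimated correlation was limited by the 2 residual degrees of freedom of the class contrasts and passed 0 lists. A list that it did not call is therefore not shown to be unmoved. List counts are also given adjusted over the list alone. Lists held 412 genes found in both tables, of which 3 were matched through an older symbol (Pvrl1, Pvrl2 and Pvrl4 for the nectins).

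Simulated counts drawn from the real means and library sizes, with 200 changed genes at a dispersion of 0.02, were used to test the procedure. For placode-like against basal cells (11914 genes), 82% of genes changed by a log2 of 1 and 100% of those changed by 2 were recovered. For suprabasal against basal cells (11263 genes) the shares were 82.8% and 96.9%, for Shh-positive against Sox9-positive cells (10531 genes) 63.9% and 95.9%, for the libraries over all cells (13551 genes) 51.0% and 95.8%, and for placode-like cells between libraries (12527 genes) 25.5% and 77.7%.

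Genes to name were chosen by a rule fixed before the data were examined: Madcam1, Sox9, Shh, Eda, Lef1, Ccnd1 and Cdkn1a in any case; from each list up to 4 members past the threshold with the largest change; and, outside the lists and the clustering genes, the 10 higher and 10 lower genes with the largest change, with the same direction in every library and a mean level of 20 CPM or more. From the genes the rule gave, those printed were picked for what they are known to do after their values had been seen. Other genes named below, in the closing observations, were also picked after their values had been seen. CPM values are summed UMIs scaled to all UMIs of the same cells, given as the mean and SD over the 3 libraries. The SE of a log2 fold change was computed from the fold change and the F value of its quasi-likelihood test. It is not the spread between libraries, which can be wider. Fold changes per library used 1 CPM as prior count.

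Depth was 36924284 UMIs in 1601 cells for the total epithelium library, 34900788 in 1511 cells for placode-enriched library 1 and 38645840 in 1571 cells for placode-enriched library 2. Intervals on shares are exact binomial (Clopper-Pearson) and on CPM exact Poisson, both at 95%, and cover counting error only. Where shares of cells with a UMI were compared, each cell was also thinned to 5000 UMIs, which left out 0 cells. Alternatives covered the test (DESeq2 1.42.0), scaling by size factors, the low-count filter, the library block, each library left out, the other set of clustering genes, all variable genes, Leiden resolutions 0.5 and 2, doublets kept and thinning. Alternatives added after seeing the data were the unnamed clusters counted as basal, the removal of cells with both Xist and Y-linked UMIs, and male cells alone. So were doublets kept for the libraries over all cells, all variable genes for the class shares, and the alternatives of the cell cycle lists. Gene positions are those of the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, and X and Y genes were taken from NCBI RefSeq on the same assembly. Genes with near-identical copies (tubulins, histones, Hspa1a and Hspa1b, Serpinb3 genes) are uncertain, since the counting rule for shared reads was not given, as is Tsix, which lies antisense to Xist.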

Results

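Single-cell RNA counts were collected from E14.5 mouse back skin epithelium as 1 total epithelium library of 1601 cells and 2 placode-enriched libraries of 1511 and 1571 cells. The median cell held 21977, 21652 and 23419 UMIs, respectively, and 4536, 4572 and 4641 genes. The design sets the hair placode against the epidermis around it, and within the same libraries allows the layers of the epidermis and the populations inside the placode to be compared.

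The placode-enriched libraries held more transcript of the sorting antigen and a larger share of placode-like cells. Madcam1 (chromosome 10, 79664559 to 79668537 on GRCm38, a protein-coding gene) stood at 3.12 CPM in the total epithelium library (95% interval 2.57 to 3.75) against 36.3 (34.3 to 38.3) and 33.4 CPM (31.6 to 35.3) in the placode-enriched libraries. A Madcam1 UMI was seen in 4.33% of cells of the total epithelium library and in 41.5% and 41.2% of cells after the sort. With cells thinned to 5000 UMIs these shares were 1.88%, 15.7% and 16.1%. In the total epithelium library, which was not gated on MAdCAM-1, the unthinned share was 2.42% in suprabasal-like cells, which should lack the gene, and 28.0% in placode-like cells, at median depths of 23930 and 17756 UMIs. In the placode-enriched libraries, where the suprabasal-like cells had been sorted by the same gate, it was 18.9% and 12.2% in these cells at 24611 and 27341.5 UMIs. Placode-like cells there were at 54.6% and 53.8% at 19474 and 20605.5 UMIs.

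Placode-like cells made up 7.85% of the total epithelium library (95% interval 6.58 to 9.28) and 57.3% (54.7 to 59.8) and 57.0% (54.5 to 59.5) of the placode-enriched libraries. Basal epidermis-like cells went the other way, at 65.5%, 18.2% and 16.4%, as did suprabasal-like cells at 20.8%, 4.91% and 5.74%. Melanoblast-like cells, the pigment cell precursors marked by Dct, Pmel and Mitf, were 20 of 1592 cells in the total epithelium library, 1 of 1507 in placode-enriched library 1 and 0 of 1568 in library 2, where the upper limit was 0.235%. The MAdCAM-1 gate sets these shares, and 1 library against 2 is too few for a permutation test to pass the threshold. Placode-like cells carried the secreted Wnt antagonist Dkk4 at 450 ± 75.5 CPM (SD, n = 3 libraries), the ectodysplasin receptor Edar at 76.4 ± 5.47 and the growth factor Fgf20 at 87.3 ± 18.1, as identity markers. Sostdc1, another of the 9 naming markers of this class, went the other way. Its mean was 403 CPM in placode-like, 553 in basal and 1065 in unnamed cells, where it was highest. Each of the remaining naming markers was highest in placode-like cells. The placode-like share of the placode-enriched libraries ranged with the clustering, down to 45.2% and 44.2% with the other set of clustering genes, which left 33.2% and 35.1% of cells unnamed. Their basal share was 30.3% and 28.0% at resolution 0.5, and their suprabasal share 1.19% and 1.21% at resolution 2.

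**Figure D1:**
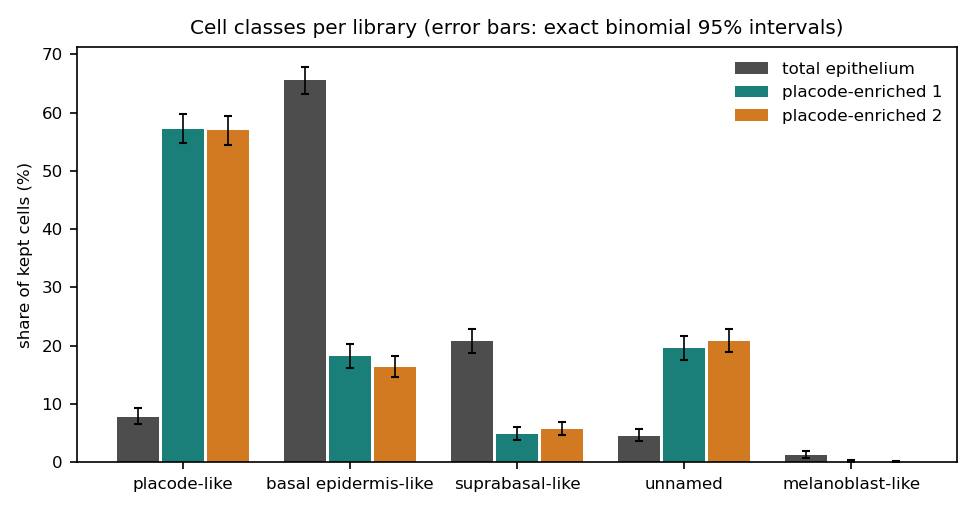
Share of kept cells (%, y axis) per class (x axis) in the total epithelium library and the 2 placode-enriched libraries. Error bars are exact binomial 95% intervals. Placode-like cells rose from 7.85% to 57.3% and 57.0%, while basal epidermis-like and suprabasal-like cells had lower shares after the sort.

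Placode-like cells were set against basal epidermis-like cells to ask how the placode differs from the surrounding epidermis. In the placode-enriched libraries the basal cells had also passed the MAdCAM-1 gate, so they were not an unselected sample of this epidermis. They held 12.4 and 12.9 CPM of Madcam1 and 18.7 and 24.1 of Sox9, against 1.24 and 6.60 in basal cells of the total epithelium library. Sp5, Wif1, Ltb and Dusp6 were among the genes higher in the placode. Sp5, a transcription factor switched on by Wnt, reached 24.9 ± 2.47 CPM against 0.725 ± 0.427 in basal cells (log2 fold change 5.36 ± 0.24 SE), and Wif1, a secreted Wnt inhibitor, 119 ± 15.1 against 8.48 ± 5.98 (4.04 ± 0.24). Ltb, the TNF-family ligand lymphotoxin beta, stood at 250 ± 34.5 against 12.5 ± 7.38 CPM (4.47 ± 0.16), and Dusp6, a phosphatase induced by Fgf signalling, at 565 ± 17 against 83.3 ± 30.8 (2.81 ± 0.12). Several Wnt ligands were lower, with Wnt4 at 60.7 ± 10.2 against 192 ± 26.2 CPM (-1.68 ± 0.05). Of 6158 genes tested, 1271 were higher and 1276 lower in placode-like cells (edgeR quasi-likelihood test).

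Lef1, a nuclear partner of beta-catenin, rose by a log2 of 0.39 ± 0.04. Of 15 measured Wnt feedback and target genes, 13 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 3.84e-08; adjusted p = 0.332 with an estimated correlation). Of 11 Wnt ligand and secretion genes, 0 rose and 9 fell, also adjusted over the list alone, among them Wnt3a at -2.48 and Wnt16 at -2.04 (camera adjusted p = 6.08e-07; adjusted p = 0.397 with an estimated correlation). The ligand Wnt10b, a naming marker of the placode-like class and not a member of this list, was at 31.5 ± 1.49 CPM in placode-like and 11.5 ± 3.10 in basal cells. In the Eda and NF-kB list 12 of 18 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 4.24e-05; adjusted p = 0.397 with an estimated correlation). The NF-kB inhibitor Tnfaip3 rose by 3.51 ± 0.18 and the chemokine Cxcl10 by 4.60 ± 0.32, while Eda, the ligand of the pathway, was lower in the placode at 1.51 ± 0.525 against 4.54 ± 1.01 CPM (-1.77 ± 0.27, adjusted p = 4.09e-05). In the Fgf list 9 of 15 rose and 3 fell, also adjusted over the list alone, including the ETS factor Etv4 at 2.71 and the receptor Fgfr1 at 2.21 (camera adjusted p = 0.00695; adjusted p = 0.397 with an estimated correlation).

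Of 30 genes for guidance cues and their receptors, 19 rose and 4 fell (21 and 4 adjusted over the list alone; camera adjusted p = 3.77e-05; adjusted p = 0.332 with an estimated correlation). The semaphorin receptor Nrp2 was up by 4.19 ± 0.15 and the Slit receptor Robo2 by 2.81 ± 0.19. In the Bmp and Tgfb list 8 of 21 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.0403; adjusted p = 0.397 with an estimated correlation). Tgfb2 rose by 5.04 ± 0.15 and Tgfb1 by 2.04 ± 0.09. Among 21 hair follicle fate genes 10 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.461 with an estimated correlation). Trps1, a zinc finger factor needed for hair, was at 114 ± 28.5 against 7.36 ± 4.39 CPM (4.09 ± 0.15). Outside the lists, Cyfip2, which acts on the actin regulator WAVE, rose by 4.37 ± 0.14, the cytokine signalling suppressor Socs2 by 2.67 ± 0.13 and the transcription factor Sox11 by 2.50 ± 0.20. Sox9, which later marks follicle stem cells, rose by 1.09 ± 0.16. Madcam1 rose by 2.46 ± 0.22 in the classes, with 4.46 in the total epithelium library and 2.22 and 2.01 in the placode-enriched ones.

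Some epidermal and attachment genes were lower in the placode, and others were higher or not past the threshold. Of 26 epidermal differentiation regulators 7 rose and 12 fell (7 and 13 adjusted over the list alone; camera adjusted p = 0.0274; adjusted p = 0.397 with an estimated correlation), with the Kruppel-like factors Klf3 and Klf5 at -2.32 and -1.29. Of 27 basement membrane and integrin genes 3 rose and 12 fell (3 and 16 adjusted over the list alone; camera adjusted p = 0.00635; adjusted p = 0.397 with an estimated correlation). Dst, a linker of keratin to hemidesmosomes, fell from 123 ± 17.5 to 29.1 ± 4.23 CPM (-2.07 ± 0.07), whereas Frem1, an extracellular matrix protein, rose by 3.02 ± 0.18. In the glycolysis and hypoxia list 2 of 20 rose and 13 fell (3 and 13 adjusted over the list alone; camera adjusted p = 0.00115; adjusted p = 0.461 with an estimated correlation), with hypoxia-induced Ndrg1 at -2.20. Gas1, a Hedgehog co-receptor, fell by 2.67 ± 0.09 on the log2 scale while the Hedgehog target Gli1 rose by 0.73 ± 0.10. Of 12 Hedgehog genes 5 rose and 3 fell (5 and 4 adjusted over the list alone), with a median of -0.06, a mean of 0.16 and a camera adjusted p of 0.991. Annexin Anxa1 (-2.57), growth factor Igf2 (-1.67) and the LIM protein Lmo1 (-2.01) were lower outside the lists.

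The remaining lists moved in both directions. Of 15 cell cycle inhibitors 6 rose and 5 fell, also adjusted over the list alone (median -0.06, mean 0.14, upward test, camera adjusted p = 0.524), with Cdkn1a up by 1.85 ± 0.21, Btg1 by 1.42 ± 0.04 and Gadd45g by 1.65 ± 0.10. Of 26 actomyosin genes 13 rose and 11 fell (0.457), also adjusted over the list alone, and the actin-binding calponin Cnn3 was at 156 ± 11.3 against 46.1 ± 6.54 CPM. Of 18 cadherin and desmosome genes 3 rose and 8 fell (0.155), of 12 Notch genes 5 rose and 4 fell (0.619), and of 19 dissociation and stress genes 9 rose and 6 fell (0.227), each the same adjusted over the list alone. The 6 fibroblast markers in both tables, chiefly Dcn and Postn, summed to 1643, 1270 and 1154 CPM in placode-like cells of the total epithelium library and placode-enriched libraries 1 and 2 and to 836, 813 and 657 in basal cells. Ccnd1 (cyclin D1) was 0.34 ± 0.07 higher, a call that ended under 4 alternatives and turned to -0.17 with the unnamed clusters counted as basal; Sox9 (0.13) and Gli1 (0.24) were then not past the threshold, nor was Sox9 with no replicate block (1.22, adjusted p = 0.0682). Counts were smaller with no replicate block (741 higher, 538 lower), with DESeq2 (750, 735) and with thinned cells (618, 619).

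**Figure D2:**
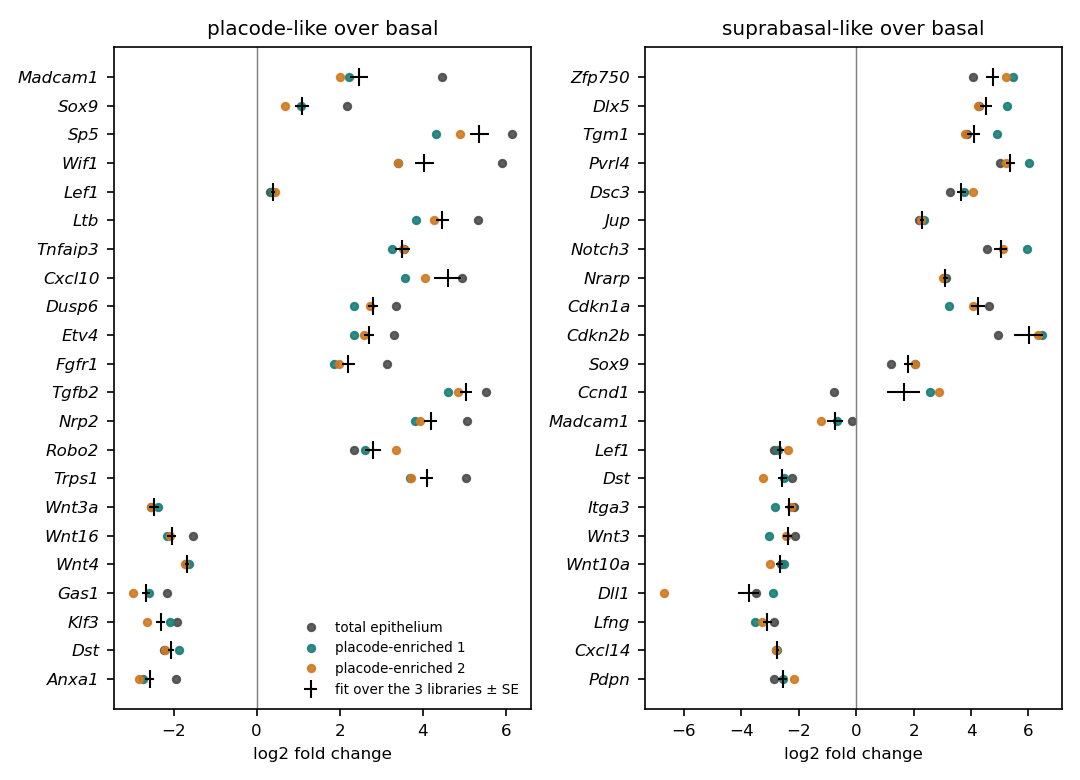
Log2 fold change (x axis) of named genes (y axis) in placode-like over basal cells (left) and suprabasal-like over basal cells (right). Coloured points are single libraries, and black bars are the fit over the 3 libraries with its SE. Sp5, Wif1, Ltb and Dusp6 lay right of 0 in every library on the left, and Ccnd1 lay on both sides of 0 on the right.

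Suprabasal-like cells, the layer that has left the basement membrane, were set against basal cells to describe stratification. In the placode-enriched libraries both classes had passed the MAdCAM-1 gate. Suprabasal-like cells there held less Krt1 (645 and 614 against 2858 CPM) and more Krt17 (3515 and 2605 against 512) than in the total epithelium library. Their numbers fell from 74 and 90 to 18 and 19 at resolution 2. The fit over the 3 libraries therefore pools suprabasal-like cells that differed between the libraries. Zfp750, Tgm1 and Notch3 were among the higher genes and Itga3 among the lower ones. Zfp750, a transcription factor of epidermal differentiation, stood at 154 ± 19.6 against 5.12 ± 2.56 CPM (log2 fold change 4.75 ± 0.23 SE). Tgm1, which cross-links the cornified envelope, was at 30.6 ± 19.7 against 1.71 ± 1.62 (4.09 ± 0.22), and Notch3 at 46.4 ± 7.23 against 1.23 ± 0.701 (5.03 ± 0.23). The integrin Itga3 fell from 31.1 ± 3.73 to 6.04 ± 0.688 CPM (-2.33 ± 0.17). Of 5792 genes tested, 849 were higher and 904 lower (edgeR quasi-likelihood test).

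Of 27 epidermal differentiation regulators 22 rose and 2 fell, also adjusted over the list alone, including Dlx5 at 4.52 (camera adjusted p = 7.21e-12; adjusted p = 0.178 with an estimated correlation). Of 19 cadherin and desmosome genes 14 rose and 2 fell, also adjusted over the list alone, including nectin 4 (Pvrl4) at 5.37 ± 0.17, desmocollin Dsc3 at 3.66 and plakoglobin (Jup) at 2.30 (camera adjusted p = 5.66e-09; adjusted p = 0.378 with an estimated correlation). Of 26 basement membrane and integrin genes 3 rose and 20 fell (4 and 21 adjusted over the list alone; camera adjusted p = 1.91e-07; adjusted p = 0.178 with an estimated correlation), Dst by 2.57 on the log2 scale (log2 fold change -2.57). Of 11 Wnt ligand genes 0 rose and 10 fell, also adjusted over the list alone, including Wnt3 at -2.39 and Wnt10a at -2.67 (camera adjusted p = 5.66e-09; adjusted p = 0.178 with an estimated correlation). In the Notch list 6 of 11 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0585). The members that rose included the receptor Notch3 and the Notch target Nrarp (3.11 ± 0.08), and those that fell the ligand Dll1 (-3.75) and the glycosyltransferase Lfng (-3.10), which modifies Notch receptors.

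Members of the Eda, Hedgehog and Wnt feedback lists were among the genes lower in suprabasal than in basal cells, while the Fgf and the Bmp and Tgfb lists moved both ways. Of 16 Eda and NF-kB genes 0 rose and 10 fell (0 and 11 adjusted over the list alone; camera adjusted p = 0.00187; adjusted p = 0.378 with an estimated correlation). The Edar adaptor Edaradd was at -1.82 and the activin inhibitor Fst at -1.73. Of 11 Hedgehog genes 0 rose and 6 fell, also adjusted over the list alone, with Gas1 at -2.61 and Cdon at -2.42 (camera adjusted p = 0.00213; adjusted p = 0.378 with an estimated correlation). Of 11 Wnt feedback genes 0 rose and 5 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0105; adjusted p = 0.378 with an estimated correlation), including Lef1 at -2.64, Fzd10 at -1.76 and Kremen2 at -1.60. Of 43 G2 and M phase genes 1 rose and 22 fell (2 and 24 adjusted over the list alone; camera adjusted p = 1.55e-05; adjusted p = 0.71 with an estimated correlation). Their sum was at 6153 against 6261 CPM in the total epithelium library and at 8086 against 10134 and 8510 against 9833 in the placode-enriched ones. Of 18 dissociation and stress genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0133; adjusted p = 0.378 with an estimated correlation). Heat shock protein Hspb1 was up by 3.39 and Fos by 2.92. Cell cycle inhibitors were 7 higher and 2 lower of 16 (8 and 2 adjusted over the list alone; camera adjusted p = 0.146), among them Cdkn1a (4.24 ± 0.24) and Cdkn2b (10.7 ± 1.40 against 0.0968 ± 0.168 CPM, with 0 in basal cells of both placode-enriched libraries, so that its fold is poorly set).

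Sox9 was higher in suprabasal cells in all 3 libraries, at 68.7 ± 47.5 against 16.5 ± 8.96 CPM (1.82 ± 0.17, adjusted p = 2.28e-05), as was keratin 17 (Krt17, 2.87 ± 0.25). With no replicate block the Sox9 call was lost (1.99, adjusted p = 0.0985), and at resolution 2 its change was 0.84. Among genes outside the lists, the GTPase Rhov (5.36), the calpain subunit Capns2 (4.97) and the lipoxygenase Alox12 (4.58) were higher and the chemokine Cxcl14 (-2.75), podoplanin (Pdpn, -2.56) and Lmo1 (-2.35) lower. Eda (-1.03, adjusted p = 0.0574), Madcam1 (-0.75, adjusted p = 0.068) and Ccnd1 (1.65, adjusted p = 0.0539) were not past the threshold, and Ccnd1 went down in the total epithelium library (-0.76) and up in the placode-enriched ones (2.56 and 2.88). Of the other lists, S phase had 4 higher and 4 lower of 39 (3 and 3 adjusted over the list alone), Bmp and Tgfb 4 and 5 of 19 (4 and 6) and guidance 5 and 9 of 27 (6 and 10). Hair fate had 6 and 9 of 17 (6 and 9), and actomyosin 9 and 5 of 27 (9 and 7). Glycolysis had 2 and 4 of 20 (2 and 4) and Fgf 3 and 4 of 12 (4 and 4). The lowest camera adjusted p of these lists was 0.187. The Fgf list had a median of 0.02, a mean of -0.11 and a downward test. The Bmp and Tgfb list had a median of -0.24, a mean of -0.06 and an upward fry test, not past the threshold (fry adjusted p = 0.876). Counts were smaller with no replicate block (538 higher, 448 lower) and with thinned cells (433, 424), and the lower count fell to 592 without placode-enriched library 1 and to 478 with DESeq2.

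Inside the placode, cells with a Shh UMI were set against cells with a Sox9 UMI. Shh (chromosome 5, 28456815 to 28467256) is the Hedgehog ligand made in the placode centre, and Sox9 (chromosome 11, 112782224 to 112787760) is known from cells at the placode edge and above. The 2 genes shared fewer cells than chance within depth deciles: 6 cells with both against 11.8 under independence in the total epithelium library (ratio 0.508, permutation p = 0.0125, two-sided). There were 129 against 164 in placode-enriched library 1 (0.788, permutation p = 1e-05, the smallest that the permutations can give) and 147 against 169 in library 2 (0.869, permutation p = 0.00213). A cell with 0 UMIs of a gene can still express it, and in the total epithelium library the ratio was 0.640 with doublets kept (permutation p = 0.0564). With 2 UMIs of each gene asked for, it was 0.376 there (1 cell against 2.66, permutation p = 0.289) and 0.584 and 0.415 in the placode-enriched libraries (permutation p = 0.00017 and 1e-05).

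Shh-positive cells held more Bmp2, a Bmp ligand, Fgf20, an Fgf ligand, and Dkk4. Bmp2 (chromosome 2, 133552159 to 133562885) stood at 227 ± 18.2 against 46.5 ± 14.2 CPM in Sox9-positive cells (2.45 ± 0.08). Fgf20 (chromosome 8, 40279166 to 40308331) was at 164 ± 51.7 against 29.3 ± 12.6 (2.60 ± 0.10) and Dkk4 (chromosome 8, 22624043 to 22627547) at 789 ± 145 against 209 ± 153 (2.31 ± 0.11). Sostdc1 (chromosome 12, 36314139 to 36318452), a secreted Bmp and Wnt antagonist, went the other way, at 141 ± 22.6 against 737 ± 105 CPM (-2.37 ± 0.05). Of 10648 genes tested, 443 were higher and 430 lower in Shh-positive cells (edgeR quasi-likelihood test, sums of 32, 269 and 308 against 35, 222 and 184 cells).

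Of 13 Wnt feedback genes 9 rose and 1 fell (11 and 1 adjusted over the list alone), with Sp5 up by 3.87 ± 0.18, Tcf7 by 1.16 and Axin2, a direct Wnt target, by 0.99, and with Ccnd1 at -0.79 (camera adjusted p = 3.98e-10; adjusted p = 0.199 with an estimated correlation). In the Eda and NF-kB list 6 of 17 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000365; adjusted p = 0.199 with an estimated correlation). The NF-kB subunit Relb rose by 0.87 ± 0.09, Ltb by 0.88 over the 3 libraries but with -0.27 in the total epithelium library, and Fst was at -1.44. The Hedgehog pathway read-outs Ptch1 (41.3 against 82.3 CPM) and Gli1 (-0.73 ± 0.15) and the co-receptor Gas1 (-2.42) were higher in Sox9-positive cells. Of 11 Hedgehog genes 1 rose and 3 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.000639; adjusted p = 0.199 with an estimated correlation). Glycolysis and hypoxia genes had 0 higher and 8 lower of 20 (0 and 12 adjusted over the list alone; camera adjusted p = 2.97e-09; adjusted p = 0.199 with an estimated correlation), with the glucose transporter Slc2a1 at -0.50 and Aldoa at -0.39. Basement membrane and integrin genes had 2 higher and 8 lower of 24 (3 and 13 adjusted over the list alone; camera adjusted p = 0.000365; adjusted p = 0.199 with an estimated correlation), including Dst (-1.04) and Lamc1 (-0.76).

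Further lists past the threshold with a preset correlation were epidermal differentiation (1 higher and 7 lower of 23, with Cebpb at -1.19), cadherins and desmosomes (1 and 5 of 16, with Perp at -0.58) and Fgf (1 and 4 of 13, with Fgfr1 at -1.06). So were guidance (7 and 2 of 28, with Robo1 at 1.14), Wnt ligands (2 and 5 of 10, with Wnt7b at -1.20), G2 and M phase (0 and 4 of 43) and S phase (0 and 1 of 39). Adjusted over the list alone, their counts were 1 and 9, 2 and 8, 2 and 4, 11 and 3, 3 and 5, 0 and 13, and 0 and 1, in the same order. With an estimated correlation, on 2 residual degrees of freedom, each of these calls was lost (adjusted p = 0.199, 0.251, 0.264, 0.309, 0.369, 0.498 and 0.534 with an estimated correlation, in the same order). Lists not past the threshold were Bmp and Tgfb (4 and 1 of 20), cell cycle inhibitors (2 and 2 of 15, median -0.01, mean 0.05, upward test) and hair fate (2 and 5 of 17, median -0.11, mean 0.07, downward test). Nor were actomyosin (5 and 3 of 25), stress (4 and 0 of 17) and Notch (0 and 1 of 11). Adjusted over the list alone these were 4 and 1, 3 and 2, 2 and 5, 6 and 4, 6 and 2, and 0 and 1.

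Outside the lists, the transcription factors Lhx2 (2.28 ± 0.15) and Ascl4 (2.02 ± 0.10) were higher in Shh-positive cells, as were Sox21 (1.66), Tgfb2 (2.46), Gadd45g (1.81), Btg1 (0.56), Madcam1 (1.34) and Lef1 (0.74) of the lists and fixed genes. The metalloreductase Steap4 (-1.56), the adhesion molecule Ncam1 (-1.05) and Selenbp1 (-1.25) were lower. Cdkn1a was 0.71 higher with an adjusted p of 0.116. Counts were 137 higher and 85 lower with no replicate block, 134 and 96 with DESeq2, 211 and 189 without placode-enriched library 1 and 230 and 216 without library 2. Gli1 lost its call without placode-enriched library 1 (-0.63), with DESeq2 and with no replicate block, Ltb with the last 2 of these, Lamc1 with DESeq2, and Aldoa, Perp and Slc2a1 with no replicate block.

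**Figure D3:**
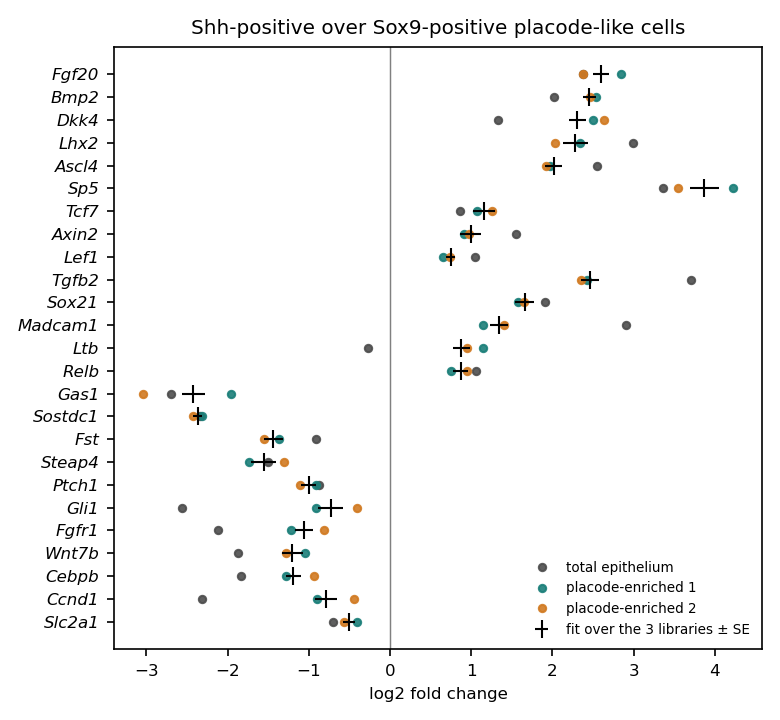
Log2 fold change (x axis) of named genes (y axis) in Shh-positive over Sox9-positive placode-like cells. Coloured points are single libraries, and black bars are the fit over the 3 libraries with its SE. Sostdc1 lay near -2.37 in every library, and Ltb lay on both sides of 0.

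Proliferation was compared through S phase and G2 and M phase genes. Mitotic genes were lower in placode-like than in basal cells. Of 43 G2 and M phase genes 0 rose and 41 fell (0 and 42 adjusted over the list alone; camera adjusted p = 7.62e-19; adjusted p = 0.397 with an estimated correlation; fry 0.0703). The mitotic kinases Plk1 and Aurka were at -0.79 ± 0.09 and -0.79 ± 0.07, and both lost their calls with no replicate block (-0.71 and -0.72) and at Leiden resolution 0.5 (-0.12 and -0.11). The list summed to 6872 against 10134 CPM in placode-enriched library 1 and 6649 against 9833 in library 2, but to 6103 against 6261 in the total epithelium library. Of 39 S phase genes 12 rose and 10 fell, also adjusted over the list alone, with a median of 0.04, a mean of -0.01 and a camera adjusted p of 0.991. This depended on the clustering, since the list passed the threshold upward with all variable genes (0.11) and at resolution 2 (0.17), and downward at resolution 0.5 (-0.13) and with the unnamed clusters counted as basal (-0.30). A cluster led by the mitotic genes Cdc20, Cenpf and Ube2c held 129 of 274 and 110 of 257 basal cells of the placode-enriched libraries and 242 of 1043 in the total epithelium library. In the placode-enriched libraries basal cells were deeper, at medians of 31130.5 and 32248 UMIs against 22004. At Leiden resolution 0.5 the G2 and M phase median turned to 0.04.

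The placode-enriched libraries were then compared with the total epithelium library over all cells, where gate and litter went together. Shh rose from 4.13 to 37.5 and 37.5 CPM (3.22 ± 0.16), Tgfb2 from 2.74 to 31.1 and 34.9 (3.63 ± 0.18), the neurotrophin Bdnf from 9.71 to 75.7 and 79.7 (3.04 ± 0.14) and Sox9 from 11.5 to 41.8 and 44.6 (1.94 ± 0.14). The suprabasal keratins Krt1 and Krt10 fell from 715 to 50.3 and 53.8 CPM (-3.74 ± 0.11) and from 970 to 103 and 106 (-3.18 ± 0.11). Of 13704 genes tested 2437 were higher and 2152 lower (edgeR quasi-likelihood test, 1 library against 2).

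By list, higher and lower genes numbered 17 and 1 of 23 for hair fate (Trps1 3.07), 19 and 0 of 31 for guidance (Nrp2 3.49), 11 and 3 of 15 for Fgf (Fgfr1 2.43, Etv4 2.18) and 11 and 3 of 20 for Eda and NF-kB (Ltb 2.85, Eda -0.88). They numbered 9 and 1 of 16 for Wnt feedback (Wif1 3.04, Lef1 0.42, Ccnd1 0.60) and 8 and 2 of 12 for Hedgehog (Ptch1 1.29). For the rest they numbered 10 and 4 of 21 for Bmp and Tgfb, 10 and 3 of 28 for basement membrane (Frem1 3.17) and 20 and 0 of 43 for G2 and M phase (Cenpf 0.89, Mki67 0.86). Adjusted over the list alone these counts were 17 and 1, 19 and 2, 11 and 3, 11 and 3, 9 and 1, 8 and 2, 10 and 4, 10 and 3, and 20 and 0. Lists with more lower than higher genes were epidermal differentiation at 4 and 16 of 30 (Tgm1 -3.02) and cadherins and desmosomes at 2 and 9 of 19 (Dsc3 -1.71). Others were glycolysis at 0 and 11 of 21 (Pgk1 -1.29, Aldoa -0.92), Wnt ligands at 0 and 6 of 13 (Wnt16 -1.16), and S phase at 2 and 8 of 39. Adjusted over the list alone these were 4 and 18, 2 and 10, 0 and 11, 0 and 6, and 2 and 7. Stress genes went both ways, at 5 and 6 of 20 (Hspb1 -2.95, Fos -2.14), or 5 and 7 adjusted over the list alone. Cell cycle inhibitors were at 6 and 5 of 16 (Cdkn1a -1.58), actomyosin at 6 and 4 of 27 and Notch at 3 and 4 of 14, and at 6 and 5, 7 and 4, and 3 and 4 adjusted over the list alone.

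Outside the lists, fibronectin (Fn1, 2.91) and the hormone Pthlh (2.64) were higher, and the cornified layer protein Krtdap (-3.53), the fatty acid elongase Elovl4 (-4.00) and galectin 3 (Lgals3, -4.52) lower. Xist, the RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254), stood at 0.109 CPM in the total epithelium library against 1000 and 924 CPM, so the libraries also differed in embryo sex. In the total epithelium library 90.3% of cells held Y-linked and no Xist UMIs, and in the placode-enriched libraries 77.9% and 71.0% held Xist and no Y-linked UMIs. Male cells alone gave 1361 higher and 1073 lower genes, and DESeq2 1072 and 926. Eda lost its call under both (adjusted p = 0.0628 and 0.282), Lef1 with male cells (adjusted p = 0.0684) and Pgk1 with DESeq2 (adjusted p = 0.108). Gate, litter and table could not be parted with 1 library against 2.

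Placode-like cells of the placode-enriched libraries were compared with those of the total epithelium library, to ask whether the gate picked particular placode cells. Past the threshold, 110 genes were higher and 166 lower of 12698 (edgeR quasi-likelihood test, 1 library against 2). In simulated counts this comparison recovered 25.5% of genes changed by a log2 of 1 and 77.7% of those changed by 2. The counts therefore do not show that the other genes were alike. The mix of placode-like clusters also differed. A cluster led by Wif1, Shh and Tgfb2 held 47 of 125 placode-like cells of the total epithelium library, against 390 of 863 and 446 of 894. Higher were Madcam1 at 58.3 and 52.5 against 30.1 CPM (0.94 ± 0.18), Tgfb2 (1.17 ± 0.20), Nrp2 (1.13), Frem1 (0.89), Trps1 (0.72), the tubulin Tubb2b (1.21, uncertain because of its close copies), Cenpf (0.79) and Mki67 (0.68). Shh (0.56, adjusted p = 0.0896), Sox9 (0.40, adjusted p = 0.284), Lef1 (0.09, adjusted p = 0.782), Ccnd1 (-0.18, adjusted p = 0.661), Eda (-0.71, adjusted p = 0.698) and Cdkn1a (-1.08, adjusted p = 0.0549) were not past the threshold.

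Lower were suprabasal genes, with Krtdap at 21.9 and 18.8 against 329 CPM (-3.96 ± 0.13), Krt1 (-2.83), Dmkn (-1.97) and Krt10 (-1.64), and the stress genes Hspb1 (-2.05 ± 0.14), Egr1 (-1.82) and Junb (-1.02). In the total epithelium library Hspb1 was highest in suprabasal-like cells, at 1981 CPM against 123 in placode-like cells, while Egr1 and Junb were not highest there. Whether RNA released by suprabasal cells added to the Hspb1 level of placode-like cells was not tested. The retinoic acid binding protein Crabp1 was at 60.1 CPM in the total epithelium library and at 1.79 and 2.40 in the others (-4.77 ± 0.24). The fibroblast markers Col1a1 (35.9 against 0.224 and 0.051 CPM), Col3a1 (30.5 against 1.06 and 0.612) and Lum (41.3 against 3.64 and 2.85), picked after their values were seen, were lower with it, while Dcn (-0.29, adjusted p = 0.216) and Postn (-0.22, adjusted p = 0.407) were not past the threshold. Over all libraries, Col1a1 was at 4.72 CPM in 1 placode-like cluster, which held 47 of the 125 placode-like cells of the total epithelium library. In the other placode-like clusters it was at 0 and 0.189 CPM. Whether few cells held the UMIs of Crabp1 and these markers was not tested. Anxa1 fell by 2.01 on the log2 scale (-2.01). Glycolysis genes were 0 higher and 5 lower of 21 (0 and 9 adjusted over the list alone), with Pgk1 (-1.43), Aldoa (-0.85) and Ldha (-0.76), and S phase genes 0 and 3 of 39 (0 and 3), with Rrm2 (-0.77) and Pcna (-0.58). G2 and M phase genes were 5 and 0 of 43 (6 and 0), stress genes 0 and 3 of 19 (0 and 3) and hair fate genes 2 and 0 of 21 (2 and 0). Each other list had at most 1 gene in a direction over all genes and at most 4 adjusted over the list alone. Some of the lower genes were not particular to placode-like cells. Basal cells of the placode-enriched libraries also held less Aldoa (508 and 560 against 864 CPM) and Hspb1 (51.8 and 61.4 against 172) than those of the total epithelium library. Both genes, with Ldha and Anxa1, were likewise lower there in suprabasal-like and unnamed cells. Male cells alone gave 17 higher and 52 lower genes, DESeq2 26 and 81; Under both, Madcam1 (0.78 and 0.93), Frem1, Trps1, Mki67, Egr1, Junb and Pcna kept their direction but lost their calls, as did Pgk1 with DESeq2.

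**Figure D4:**
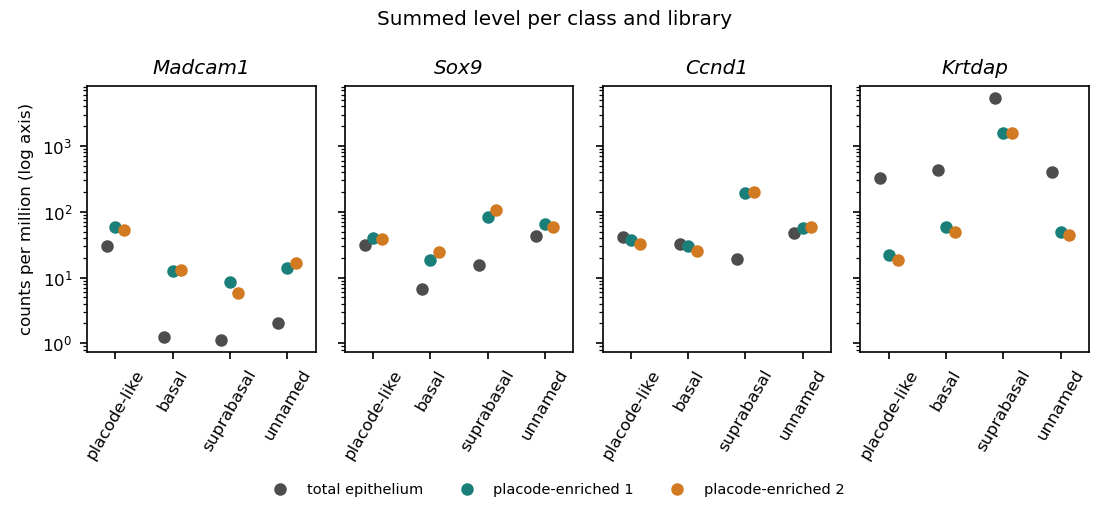
Summed level (CPM, log axis) of Madcam1, Sox9, Ccnd1 and Krtdap (panels) in 4 cell classes (x axis). Points are single libraries, with 1 total epithelium library and 2 placode-enriched ones. Ccnd1 in suprabasal-like cells was at 191 and 199 CPM in the placode-enriched libraries and 18.8 in the total epithelium library.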

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

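The interaction tests, the free RNA tests, the doublet test of the suprabasal genes, the sex test over all cells and the splits were chosen after the results were seen. The interaction test asked, for each named gene, whether its log2 fold change between classes differed between the placode-enriched libraries and the total epithelium library. It rested on 1 library against 2, and values are log2 differences, placode-enriched minus total epithelium.

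In placode-like over basal cells 16 of 40 named genes differed, and placode genes were less far above the basal class after the sort: Madcam1 -2.44, Wif1 -2.57, Sox11 -1.75, Frem1 -1.71, Trps1 -1.41, Ltb -1.36, Sox9 -1.34, Nrp2 -1.30, Fgfr1 -1.27, Socs2 -1.01, Etv4 -0.88 and Dusp6 -0.85. Plk1 (-0.79), Anxa1 (-0.89), Lmo1 (-0.83) and Gas1 (-0.65) were further below it. Madcam1 was 4.46 higher in the total epithelium library and 2.22 and 2.01 higher in the placode-enriched ones, and basal cells that had passed the MAdCAM-1 gate held 12.4 and 12.9 CPM of Madcam1 against 1.24 in basal cells of the total epithelium library. In Shh-positive over Sox9-positive cells 2 of 35 named genes differed, Ltb (1.34) and Dkk4 (1.25).

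In suprabasal over basal cells 13 of 36 named genes differed. The contrast was larger after the sort for Rhov (3.70), Ccnd1 (3.52), Krt17 (1.5), Zfp750 (1.29), Capns2 (0.99), Sox9 (0.82) and Dsc3 (0.66), and smaller for Cdkn1a (-0.99). For Rhov, Capns2 and Dsc3 the basal level was lower after the sort (Rhov 0.239 and 0.608 against 6.47 CPM), and the suprabasal level was not higher (Rhov 115 and 121 against 127 CPM). The lower genes Fst (1.19), Gas1 (0.56) and Kremen2 (0.50) were less far below the basal class, and Dst (-0.64) and Lmo1 (-0.43) further below. Set directly against each other, suprabasal-like cells of the placode-enriched libraries had 1162 genes higher and 942 lower of 10278 than those of the total epithelium library (DESeq2 193 and 130). Ccnd1 stood at 191 and 199 against 18.8 CPM, Sox9 at 83.7 and 107 against 15.5, Krt17 at 3515 and 2605 against 512, and the sebaceous and infundibular keratin Krt79 at 12.7 and 18.0 against 2.46. Krt1 (-2.20), Krt10 (-2.03), Tgm3 (-2.92) and Lgals3 (-2.76) were lower, and Krt14 (0.16, adjusted p = 0.418) and Krt5 (0.21, adjusted p = 0.244) were not past the threshold. Other genes higher in suprabasal-like than in basal cells of each library were not lower, with Calm4 at 217 and 168 against 89.1 CPM and Jup at 496 and 463 against 441. All these genes were picked after their values had been seen.

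For these higher genes, 1132 of them outside X and Y, free RNA from the other cells would keep levels below those over all cells of the library, if free RNA has the make-up of all cells; 37.7% of the genes (427) lay above that level in both placode-enriched libraries, which argues against it as the whole cause. Embryo sex is argued against as well: in male cells the median log2 ratio was 1.01 against 0.90 in all cells, 1.13 times as large, though from 11 and 10 male cells per placode-enriched library. The 2 ratios shared 301 of the 331 suprabasal-like cells of the total epithelium library, which can bring them closer. Doublets of a suprabasal cell with another cell stay open, since 7.42% of the genes (84, Ccnd1, Krt79 and Alcam among them) were 1.5 times or more above every other class, too few to decide for the rest. No biological explanation was tested, as gate and litter go together. At resolution 2 the suprabasal class held 18 and 19 cells of the placode-enriched libraries and Ccnd1 was at -1.06.

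Placode-like cells of the total epithelium library carried suprabasal transcripts. Krtdap stood at 329 CPM against 21.9 and 18.8 in the placode-enriched libraries, and 99.2% of these cells had a Krtdap UMI (median 6), against 33.7% and 31.3%. Doublets or cells of mixed identity would gather the UMIs in few cells, but the 6 of 125 cells with most held 13.9% of them, which argues against these. Free RNA of suprabasal cells stays open: 5 suprabasal markers were at a median of 21.8% of their level over the library and 3 melanoblast markers at 12.2% (95% interval 6.29 to 21.3, from 12 UMIs), a ratio of 1.79. The transcripts were not particular to placode-like cells of this library. Krtdap was also at 426 CPM in its basal, 398 in its unnamed and 310 in its melanoblast-like cells. Krt10 was at 170, 153 and 153 CPM in these classes, against 169 in placode-like cells. No biological explanation was tested.

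Over all cells the libraries differed in 4456 genes outside X and Y. Embryo sex is argued against as the whole cause, since in male cells alone the log2 fold changes had a slope of 1.12 on those of all cells and 99.98% of the 4053 genes fitted kept their direction. The 2 comparisons shared 1437 of the 1592 cells of the total epithelium library, and the genes were those past the threshold over all cells. Both can raise the slope and the shared direction in part. Class shares set by the gate stay open: expected on observed log2 ratios had a slope of 0.535, and 89.1% of the genes had the direction expected from the shares. Krt1 was at -3.76 with -1.43 expected, Pgk1 at -1.29 with 0.11 expected and Crabp1 at -1.01 with 2.22 expected. Litter and gate were confounded and untested.

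The 3 sums of a class against 3 of another make 10 splits, too few for a share under 0.05. Every other split mixed the classes within a side, so the class difference entered the residual spread and few calls could arise. The low counts of the other splits therefore cannot decide the question. For placode-like against basal cells 1 split, the real one, gave as many genes (2547, highest other 0), and likewise 1 for suprabasal against basal cells (1753, highest other 0) and 1 for Shh-positive against Sox9-positive cells (873, highest other 0).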

How the results depend on the processing

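Chosen after seeing the data were male cells alone, cells with both Xist and Y-linked UMIs left out, unnamed clusters counted as basal, doublets kept for the libraries over all cells, all variable genes for the class shares, and the alternatives of the cell cycle lists. Of the values of named genes, 582 of 594 kept direction and side of the threshold for placode-like against basal cells (11 no longer past it), 484 of 494 for suprabasal against basal (1 no longer past it, 8 newly past), 374 of 385 for Shh-positive against Sox9-positive (9 and 2), 225 of 237 for the libraries over all cells (4 no longer past, 8 moved by more than the spread) and 101 of 118 for placode-like cells between libraries (16 no longer past). Turned in sign were Ccnd1 in placode-like cells with unnamed clusters counted as basal (-0.17), Ccnd1 in suprabasal cells at resolution 2 (-1.06), Lef1 in placode-like cells between libraries with male cells alone (-0.011) and the G2 and M phase median at resolution 0.5 (0.044). The S phase median, not past the threshold at 0.04, turned to -0.13 at resolution 0.5 and -0.30 with unnamed clusters counted as basal, both past it, and to between -0.08 and -0.01 with no replicate block, without placode-enriched library 1, with thinned cells and with doublets kept; the cause was not tested.

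Genes higher and lower numbered 750 and 735 (DESeq2), 741 and 538 (no replicate block) and 618 and 619 (thinned) for placode-like against basal cells; 538 and 448 (no replicate block) and 433 and 424 (thinned), with 478 lower (DESeq2), for suprabasal against basal; 134 and 96 (DESeq2) and 137 and 85 (no replicate block) for Shh-positive against Sox9-positive; 1072 and 926 (DESeq2) and 1361 and 1073 (male cells) for the libraries; and 26 and 81 (DESeq2) and 17 and 52 (male cells) for placode-like cells between libraries. Without each library in turn they ranged from 877 to 1424 and 858 to 1400, from 671 to 1037 and 592 to 1014, and from 211 to 597 and 189 to 579 for the class contrasts in this order. Thinning and male cells leave fewer UMIs; for the others the cause was not tested.

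Shares of placode-like, basal and suprabasal cells moved as follows (%). At resolution 0.5: total epithelium basal 73.1, suprabasal 17.9; placode-enriched 1 and 2 placode-like 65.6 and 67.2, basal 30.3 and 28.0. At resolution 2: total epithelium suprabasal 15.3; placode-like 46.8 and 52.7, suprabasal 1.19 and 1.21. With the other gene set: placode-like 45.2 and 44.2. With doublets kept: placode-like 53.5 and 53.3, suprabasal 3.71 and 4.14. With all variable genes: placode-like 52.0 and 54.0, basal 23.8 and 22.8. Thinned cells gave Madcam1 at 4.27, 40.2 and 39.9 CPM, since each cell then weighs alike. Co-detection of Shh and Sox9 in the total epithelium library was at 0.640 (permutation p = 0.0564) with doublets kept and at 0.376 (permutation p = 0.289) with 2 UMIs. Lists past the threshold for the 3 class contrasts were 11, 9 and 12 with the preset correlation, 0, 0 and 0 with an estimated one, and 12, 10 and 1 with fry. Past it with fry alone were cadherins and desmosomes, Notch and cell cycle inhibitors in placode-like against basal cells (fry adjusted p = 0.0284, 0.0294 and 0.0390). In suprabasal against basal cells these were Notch and cell cycle inhibitors (fry adjusted p = 0.0127 and 0.0359). G2 and M phase in both contrasts, and glycolysis in the first, passed with the preset correlation but not with fry.

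The S phase median passed the threshold at 0.11 (all variable genes), -0.13 (resolution 0.5), 0.17 (resolution 2) and -0.30 (unnamed as basal). The G2 and M phase median of -0.48 was not past it with an estimated correlation (adjusted p = 0.397) or fry (adjusted p = 0.0703). Without each library in turn the medians ranged from -0.57 to -0.38 (G2 and M phase) and -0.03 to 0.07 (S phase). Apart from the thinning and the unnamed cells counted as basal, noted above, the cause was not tested. The filters on genes and mitochondrial UMIs removed 0 cells and gave no other value. No paired analysis was possible because the libraries compared were 1 against 2 and shared only replicate number 1. Depth limits shares of cells with a UMI for genes as low as Madcam1.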

Other observations

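All comparisons in this part were chosen after the data had been seen, as were the genes named.

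The unnamed clusters differed from both placode-like and basal cells, but came close to the naming rule for basal cells. Each met 6 of 7 basal markers and missed Krt15, at 1027 and 720 CPM against 2368 in the highest cluster. At resolution 0.5, 0 cells were unnamed. Against basal cells, 569 genes were higher and 527 lower of 5798. Sox9 stood at 55.7 against 16.5 CPM (1.71), Dusp6 at 312 against 83.3 (1.88), and Lgr6, a stem cell marker of the upper follicle (1.70), Krt17 (1.72), Etv4 (1.83) and the Hedgehog targets Ptch1 (1.21) and Gli1 (1.09) were also higher. The replication genes Pcna (0.79) and Mcm5 (0.74) were higher and the mitotic kinases Plk1 (-1.98) and Aurka (-1.99) lower, as was Lef1 (-0.53), while Madcam1 (0.28, adjusted p = 0.211) was not past the threshold. Against placode-like cells, 1033 genes were higher and 1000 lower of 5816: Tgfb2 (-3.54), Cyfip2 (-3.77) and Ltb (-2.43) were lower, and Gas1 (2.14), Anxa1 (2.08), Dst (1.34), Sox9 (0.64), Ptch1 (0.52) and Ccnd1 (0.68) higher. G2 and M phase genes summed to 4184, 4540 and 4541 CPM in these cells, below the placode-like, basal and suprabasal-like cells of the same library.

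Basal epidermis-like cells of the placode-enriched libraries had 972 genes higher and 662 lower of 11622 than those of the total epithelium library (DESeq2 166 and 79; no low-count filter 353 and 213), with Madcam1 (3.39), Sox9 (1.76), Cenpf (1.58) and Mki67 (1.35) higher and Krtdap (-2.93) and Krt1 (-2.44) lower. The make-up of the class differed too, with 129 of 274 and 110 of 257 cells in the cluster led by Cdc20, Cenpf and Ube2c, against 242 of 1043. Over all libraries this cluster held Sox9 at 23.5 CPM, against 6.85 and 6.73 in the other basal clusters. Cluster make-up and library were not parted.

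Embryo sex was read from Xist and Y-linked UMIs. In the total epithelium library 0 cells had Xist UMIs alone and 4 had both kinds, and in the placode-enriched libraries 185 and 202 cells had both (12.3% and 12.9%), of which 122 and 151 held only 1 or 2 Xist UMIs and 46 and 36 held 10 or more, against 4 and 3 called doublets. Male against female cells within the placode-enriched libraries gave 5 genes higher (Eif2s3y, Ddx3y, Uty, Kdm5d and Xlr3b) and 3 lower (Xist, Tsix and Eif2s3x) of 12475, with 366 at an unadjusted p under 0.05.

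The melanoblast markers summed to 53.5, 4.49 and 2.26 CPM over the libraries, the Schwann cell markers to 22, 17.7 and 19.6, the endothelial marker to 1.53, 1.41 and 1.53, the immune marker to 0.219, 0.230 and 0.233, the muscle markers to 1.07, 1.44 and 1.43 and the erythroid markers to 3.01, 0.288 and 0.415. The 9 periderm markers summed to 118, 147 and 141 CPM in placode-like cells against 59.9, 68.5 and 67.8 in basal cells, Krt18 being at 26.3 against 5.08.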
